A study of Mus musculus with 6 samples.

How the data were processed

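RNA from olfactory epithelium of 1-day-old mouse pups was measured on 6 expression arrays, 3 from wild-type pups and 3 from mutant pups, with 1 array per pup. Per the labels, the pups were of a mixed C57Black6/J and 129SvJ strain background, total RNA was extracted with a column kit, and RNA was amplified into biotin-labelled cDNA before hybridisation. The labels call the second group mutant, and the title of the series names KLF7, a Krüppel-like zinc finger transcription factor of neurons, as the factor whose targets were sought. Groups and replicate numbers were taken from the sample titles.

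The deposited table holds 1 intensity per probe set and array on a linear scale. How the authors condensed probes into these intensities, how they corrected background and whether they scaled arrays is not given in the sources used here. The table holds 45037 probe sets, of which 5.39% of the values were exactly 0. The quartiles of the 6 arrays differed by 0.63, 0.69 and 0.54 on the log2 scale for the lower quartile, median and upper quartile. Because these exceeded 0.1, the arrays were quantile normalized, as fixed before the data were examined. Values were then raised to a floor at the 20th percentile of all values, an intensity of 12.56, and log2 was taken. A fold change of a gene near this floor is understated.

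Probe sets were named from the platform annotation in the Gene Expression Omnibus. Of the probe sets, 34945 carried 1 gene symbol, 932 several and 9160 none in that annotation; those with several or none entered no named result. Entrez numbers of 34741 single-gene probe sets were found in the RefSeq gene table of assembly GCF_000001635.26 (GRCm38.p6), which changed 0 symbols and was used only for names and for which genes neighbour each other. The files name no genome build, so no coordinates are given. For each of 18193 genes the single-gene probe set with the highest mean over the 6 arrays was kept. Genes with a mean in the lowest 40% of single-gene probe sets, below 5.19 on the log2 scale, were left out as dim, which removed 5490 genes and left 12703 for testing. Among unnamed or multiply named probe sets above the same level, 3779 in number, limma called 0, with 8 at an unadjusted p under 0.05.

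Mutant and wild-type arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Klf7 probe sets were taken from a fit of all probe sets without the dim filter, adjusted over the Klf7 probe sets, with an exact two-sided permutation test beside them, for which 3 arrays against 3 cannot give a p below 0.1. Gene lists for cell types of the nasal epithelium and of tissue that a dissection can carry along, for neuronal gene groups, and for stress, sex and RNA quality were written before the data were examined and hold 525 genes, of which 478 had a single-gene probe set and 410 were tested. The 29 lists with at least 5 genes tested were compared with all other genes by camera in limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives. Adjustment over the list alone was given for list members. Olfactory receptor genes were tested with camera without the dim filter, and genes within 10 Mb of Klf7 with camera and Fisher's exact test.

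The genes named were fixed by rule before the data were examined. Klf7, Omp, Gap43, L1cam, Cdkn1a, Cdkn1b, Neurog1, Neurod1 and Map2 are always named; other genes that the rule lists are not reported here. To these come 12 genes in each direction, those past the threshold with the largest change and groups that do not overlap, filled up with the genes of smallest unadjusted p whose groups do not overlap. Up to 4 members of each list described are named by smallest p. Clone names were skipped, which passed over 2 genes on the higher side.

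The replicate numbers come from the labels, which do not say what a number shares. The deviations from the group means of wild-type and mutant arrays with the same number correlated across the genes tested at 0.47, 0.18 and 0.56 for numbers 1, 2 and 3. All exceeded 0.1, so the numbers were taken to pair the arrays. Deviations from a group mean sum to 0, and both arrays numbered 3 stood apart. That alone favours positive correlations among numbers 1 and 2, so for these the bar of 0.1 is weak evidence of pairing. Wild-type array 1 correlated at 0.09 with mutant array 2. Number 2 did not set its pair apart: wild-type array 2 correlated at 0.22 with mutant array 1, and their log2 levels at 0.937 (Pearson's r across the genes tested) against 0.906 with mutant array 2. The fit with the replicate number as a block was run as an alternative. Other alternatives changed the dim filter, the normalization, the floor, the variance model, array weights, the choice of probe set, the threshold, the distance from Klf7 and the set test, or left out each array in turn. Leaving out both arrays numbered 3 was added after the data were seen.

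The procedure was tested on simulated arrays with known changes. In a simulation of the mutant and wild-type comparison with independent arrays and 12713 genes, limma recovered 24 of 80 genes changed by 2 on the log2 scale and 44 of 75 changed by 3, with 5 false calls; with the replicate number as a block it recovered 7 of 80 and 22 of 75, with 0 false calls. With pair effects shared by same-numbered arrays, set to take 0.5 of the variance, and 12724 genes, it recovered 34 of 84 and 44 of 71, with 1 false call, and with the replicate number as a block 35 of 84 and 41 of 71, with 1 false call. Of unchanged genes, 1.5% then had an unadjusted p under 0.05 without the block and 4.8% with it, against 5.3% in both fits of independent arrays. The groups did not overlap for 4.7% of unchanged genes with shared pair effects and for 10.3% with independent arrays. By camera, the p of a simulated shifted list was 9e-09 and that of a simulated unshifted list 0.66 on independent arrays, and 7.4e-09 and 0.87 with shared pair effects. The simulated genes varied independently of each other, so these p do not test whether camera's preset correlation held in the data. The number of arrays limits the precision of every comparison. Plots were drawn with matplotlib 3.10.9.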

Results

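Olfactory epithelium lines the back of the nasal cavity and holds sensory neurons, their progenitors, and supporting and gland cells. Its RNA was profiled on 3 arrays from wild-type and 3 arrays from mutant mouse pups aged 1 day. Total deposited intensity ran from 10064207 on wild-type array 3 to 14439788 on mutant array 2, and array medians from 38.21 to 61.59. On any pair of arrays, at most 0.03% of the probe sets above 0 on the first held exactly equal values. Rank correlations of the deposited intensities between wild-type arrays were 0.73 to 0.872 (Spearman's rho, across probe sets, which are not independent replicates). Arrays with the same number correlated at 0.923, 0.891 and 0.883 across genotypes, and wild-type array 2 with mutant array 1 at 0.873. The first principal component carried 50.2% of the variance and set wild-type array 3 at 98.2 and mutant array 3 at 49.5, with the other 4 arrays between -42.4 and -32.3.

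The title of the series names targets of the transcription factor KLF7 as the question, so the level of Klf7 itself comes first. All 4 Klf7 probe sets were lower in the mutant arrays, with no overlap between the groups. Probe set 1419354_at fell by 3.06 on the log2 scale (SE 0.49), from 8.99 ± 0.39 to 5.94 ± 0.82 (SD, n = 3 each), which is 8.32-fold lower (limma, adjusted p = 0.00361 over the 4 probe sets). Probe set 1449439_at fell by 2.15 (SE 0.55), from 9.36 ± 0.57 to 7.21 ± 0.93, 4.44-fold lower (limma, adjusted p = 0.0173). Probe sets 1419355_at and 1419356_at fell by 2.23 (SE 0.76) and by 2.28 (SE 0.79), each with limma adjusted p = 0.0297. On both of these, mutant array 3 lay at the floor, so the 4.68-fold and 4.84-fold lower levels are understated. The exact permutation p was 0.1 for each probe set, the smallest that 3 arrays against 3 can give. Where the probe sets lie relative to the mutation is not given in the sources used here, so residual signal does not measure residual function.

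The call for 1419354_at held when any 1 array was left out. That for 1449439_at was lost without wild-type array 1 (limma, adjusted p = 0.069). That for 1419355_at was lost without wild-type array 1, wild-type array 2, mutant array 1 or mutant array 3 (limma, adjusted p = 0.098, 0.079, 0.075 and 0.082), and that for 1419356_at without the same arrays (0.11, 0.085, 0.075 and 0.065). Without both arrays numbered 3, adjusted p was 0.066 for 1419354_at and 0.07 for each of the others.

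**Figure D1:**
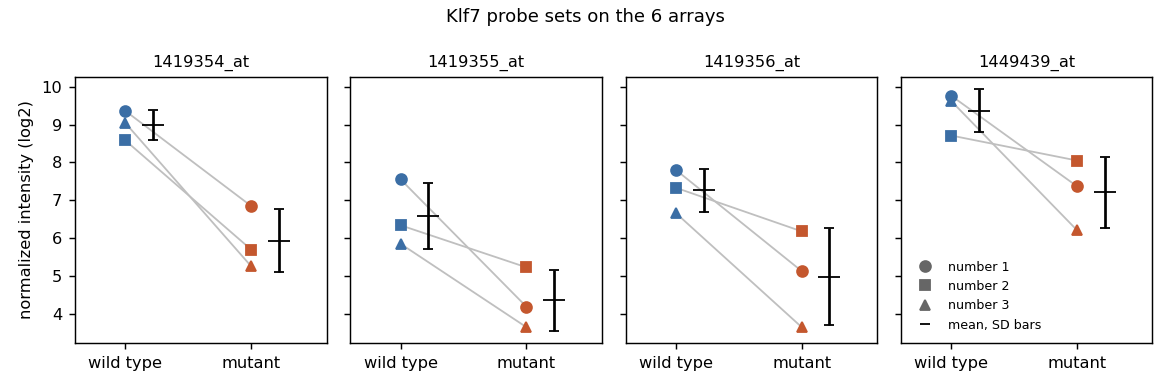
Normalized log2 intensity of the 4 Klf7 probe sets on each array, by genotype, with marker shapes for the replicate number, grey lines joining arrays with the same number, and bars for the mean and SD (n = 3 each). All mutant values lie below all wild-type values in each panel, for 1419354_at at 5.94 ± 0.82 against 8.99 ± 0.39.

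Across all genes, no single gene separated the mutant from the wild-type arrays past the threshold. With limma, 0 of 12703 genes passed the threshold and the smallest adjusted p was 1. At an unadjusted p under 0.05 there were 76 genes, 56 lower and 20 higher in the mutant, or 0.6% of those tested. With no change, independent arrays would give 635, or 5%; simulated arrays with shared pair effects gave 1.5% of unchanged genes in this fit and 4.8% in the fit with the replicate number as a block. With the replicate number as a block, limma again called 0 genes, with 157 at an unadjusted p under 0.05 (101 lower and 56 higher, 1.24% of those tested), 73 of them among the 76. The groups did not overlap for 363 genes, or 2.9%, where chance gives 10% for independent arrays and simulated unchanged genes with shared pair effects gave 4.7%; 248 of the 363 were lower in the mutant. The count of 76 became 212 without wild-type array 2, 132 without wild-type array 3 and 120 without both arrays numbered 3. The excess of lower genes depended on the arrays used: without wild-type array 1, 32 of 107 were lower, and without wild-type array 2, 84 of 212. With array medians set equal in place of quantile normalization, 25 of 41 were lower.

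This paragraph names the lower genes and the next the higher genes with the smallest unadjusted p, by a rule fixed in advance; no theme among them was tested. All those named in these paragraphs missed the threshold, with an adjusted p of 1 (limma), and had groups that did not overlap. Kif5a, a neuronal kinesin motor, had a log2 difference, mutant minus wild type, of -1.35 (SE 0.287, 2.55-fold lower). Prph (peripherin) and Ina (alpha-internexin), intermediate filament proteins of neurons, had differences of -2.74 (SE 0.698) and -1.32 (SE 0.351). For Prph 1 mutant array lay at the floor. Uchl1, a ubiquitin hydrolase abundant in neurons, differed by -1.35 (SE 0.341, 2.54-fold lower). Stmn3 and Stmn2, which regulate microtubules in growing neurites, differed by -0.80 (SE 0.187) and -0.94 (SE 0.226). Stoml3 and Gnal, proteins of olfactory cilia, differed by -0.86 (SE 0.238) and -0.92 (SE 0.257). Carns1, the carnosine synthase, differed by -1.72 (SE 0.451), Ndrg4 by -1.37 (SE 0.364) and Gramd1c by -1.46 (SE 0.395). Klf7 was also among these 12 genes.

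On the higher side, Myt1l, a zinc finger transcription factor of neurons, had a log2 difference of 1.16 (SE 0.291, 2.23-fold). Lpin1, a phosphatidate phosphatase, differed by 1.47 (SE 0.45), Gabra2, a GABA receptor subunit, by 1.41 (SE 0.536), and Stil, a centriole protein, by 1.08 (SE 0.445). Vtn (vitronectin) differed by 1.79 (SE 0.757), with 1 wild-type array at the floor. Notch1 differed by 0.59 (SE 0.249), Atp7b, a copper transporter, by 0.61 (SE 0.256), Pan3 by 0.54 (SE 0.201) and Errfi1 by 0.44 (SE 0.192). Itga9, Fam161a and Lancl1 differed by 1.32 (SE 0.603), 0.49 (SE 0.225) and 0.83 (SE 0.381), with unadjusted p of 0.0508, 0.0514 and 0.0526 by limma; Lancl1 is one of the genes within 10 Mb of Klf7.

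Of the other genes named in advance and reported here, none passed the threshold (limma, adjusted p = 1 for each). L1cam, an axonal cell adhesion molecule, had a mean of 8.79 ± 0.41 in wild type and 7.35 ± 0.92 in mutant (SD, n = 3 each), a difference of -1.44 (SE 0.513) with no overlap. Gap43, a growth cone protein of immature neurons, differed by -0.73 (SE 0.342). Map2, a microtubule protein of dendrites, differed by -0.90 (SE 0.355), but by 0.1 when all its probe sets were averaged, and it is one of the genes within 10 Mb of Klf7. Omp, a marker of mature olfactory neurons, differed by -0.36 (SE 0.48) and by 0.02 without wild-type array 1. The cell cycle inhibitor Cdkn1a differed by -0.53 (SE 0.503) and by 0.09 without mutant array 2, and Cdkn1b by 0.47 (SE 0.202). The neuronal differentiation factors Neurod1 and Neurog1 differed by 0.32 (SE 0.232) and -0.79 (SE 1.033).

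Gene lists of neurons shifted by camera with the preset correlation where single genes did not pass. A camera p of that kind weighs the shift against the spread over genes and not over the 3 pups of each group. It does not measure how far the shift would recur in other pups. Genes of mature olfactory sensory neurons fell as a set in the mutant: 13 of 15 were lower, with a median log2 difference of -0.71, or 1.64-fold (camera, adjusted p = 7.6e-13; adjusted p = 0.085 with an estimated correlation). Over all genes tested, 0 of the 15 passed; adjusted over the list alone, 4 did. These were the ciliary protein Stoml3, from 10.54 ± 0.11 to 9.67 ± 0.18 (limma, adjusted p = 0.032 over the list alone), the olfactory G protein subunit Gnal, from 10.27 ± 0.08 to 9.35 ± 0.22 (0.032), the vesicular glutamate transporter Slc17a6, from 9.94 ± 0.21 to 8.89 ± 0.44 (0.0348), and the G protein subunit Gng13, from 10.56 ± 0.39 to 9.74 ± 0.20 (0.0446). With the replicate number as a block, the olfactory channel subunit Cnga2 (difference -1.41) and Cartpt (difference -0.90) also passed over the list alone, each with limma adjusted p = 0.0282, against 0.0573 and 0.0703 without it. The median was negative for arrays numbered 1, 2 and 3 (-0.84, -0.57 and -0.39), and 10 of the 15 genes were lower within each of these pairs. The 2 members that were higher in the mutant were Cngb1 (difference 0.73, SE 0.689) and Adcy3 (0.36, SE 0.45).

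Neuronal cytoskeleton genes fell as a set with a median log2 difference of -0.25 and 20 of 25 lower (camera, adjusted p = 2.5e-11; adjusted p = 0.08 with an estimated correlation). Over all genes tested 0 passed, and adjusted over the list alone 2 did, Stmn3 and Stmn2, both with limma adjusted p = 0.02. Synaptic vesicle genes fell as a set, with 13 of 13 lower and a median of -0.43 (camera, adjusted p = 5.7e-09; adjusted p = 0.08 with an estimated correlation). None of these 13 passed over all genes or adjusted over the list alone by limma, with 3 at an unadjusted p under 0.05. Those 3 were the vesicle protein Syp (difference -0.93, SE 0.371), the membrane fusion protein Stx1a (-1.32, SE 0.554) and the calcium sensor Syt1 (-1.07, SE 0.464). Rab3b differed by -1.20 (SE 0.633). Genes of immature olfactory sensory neurons, of which 10 were also in the cytoskeleton list, fell by a smaller median of -0.19, with 14 of 20 lower (camera, adjusted p = 0.0023; adjusted p = 0.14 with an estimated correlation). Over all genes tested 0 of these passed, and adjusted over the list alone 1 did, Stmn2 (limma, adjusted p = 0.032). Crmp1 and Tubb3 differed by -1.28 (SE 0.672) and -0.84 (SE 0.475). The largest falls of the list, in Crmp1, Stmn2, Tubb3 and Gap43, were all in genes shared with the cytoskeleton list. Members not shared went both ways. Trib3, Gng8, Ebf3, Cxcr4 and Ebf1 differed by -0.63, -0.27, -0.07, -0.05 and -0.004. Ncam1, Marcksl1, Emx2, Nhlh2 and Lhx2 differed by 0.005, 0.02, 0.08, 0.19 and 0.62. The fall of the immature list is thus not separate from that of the cytoskeleton list. The immature list was no longer called without wild-type array 1 (camera, adjusted p = 0.11, median -0.08) or mutant array 1 (0.10, median -0.16).

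**Figure D2:**
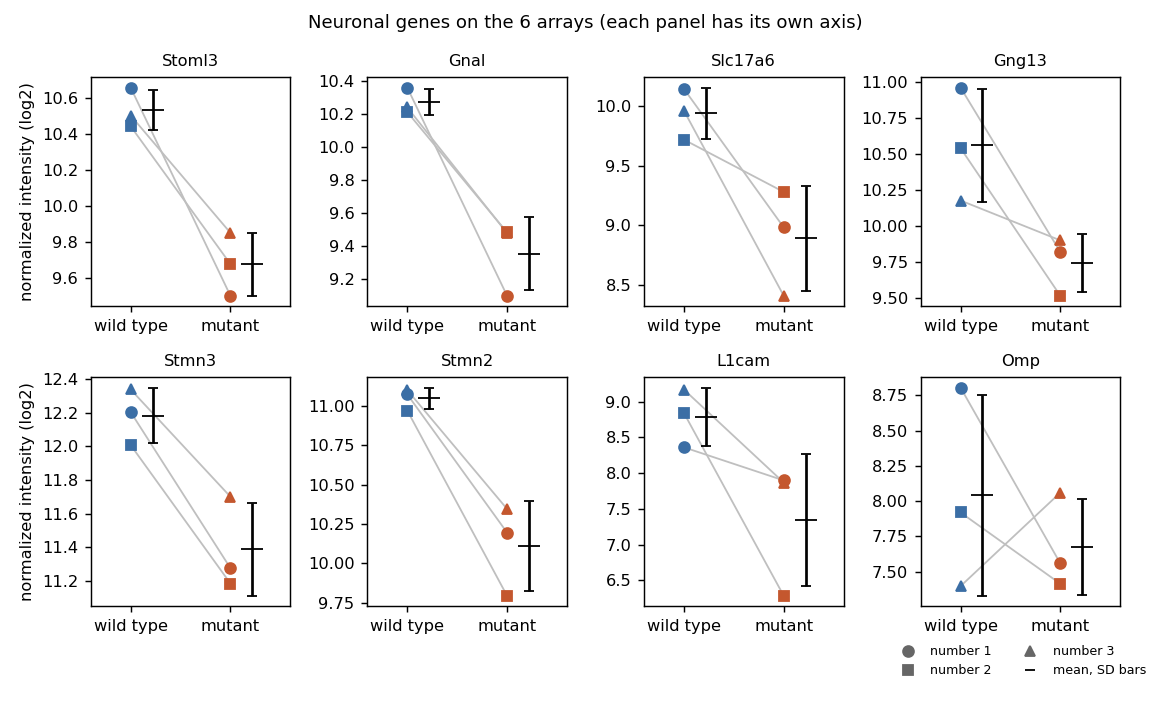
Normalized log2 intensity of 8 neuronal genes on each array, by genotype, with marker shapes for the replicate number, grey lines joining arrays with the same number, and bars for the mean and SD (n = 3 each); each panel has its own axis, which does not start at 0. Wild-type and mutant values do not overlap for Stoml3, Gnal, Slc17a6, Gng13, Stmn3, Stmn2 and L1cam, and overlap for Omp.

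Genes of axon guidance and cell adhesion fell as a set with a median of -0.15 and 16 of 25 lower (camera, adjusted p = 0.028; adjusted p = 0.28 with an estimated correlation). L1cam led the list, followed by Ncam2 (-0.55, SE 0.291), Kirrel3 (-0.82, SE 0.537) and Epha5 (-0.66, SE 0.554). Over all genes or adjusted over the list alone limma called 0 of them, with 1 at an unadjusted p under 0.05. The call was lost without any array but mutant array 2: camera adjusted p was 0.23, 0.072 and 0.069 without wild-type arrays 1, 2 and 3, and 0.10 and 0.37 without mutant arrays 1 and 3. Without both arrays numbered 3 it was 0.25.

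Lists outside neuronal structure gave 3 further falls. Genes of the unfolded protein response, which protein load in the endoplasmic reticulum induces, fell as a set with a median of -0.24 and 12 of 14 lower (camera, adjusted p = 0.0023; adjusted p = 0.26 with an estimated correlation). Among them Atf5 differed by -0.33 (SE 0.159), Trib3 by -0.63 (SE 0.458), the chaperone cofactor Sdf2l1 by -0.90 (SE 0.672) and Dnajb9 by -0.27 (SE 0.217). That call was lost without mutant array 1 (camera, adjusted p = 0.10). Cholesterol synthesis genes fell with a median of -0.23 and 12 of 14 lower (camera, adjusted p = 0.0023; adjusted p = 0.37 with an estimated correlation), among them Fdft1 (-0.54, SE 0.295), Sc5d (-1.19, SE 0.879), Hmgcs1 (-0.21, SE 0.175) and Fdps (-0.65, SE 0.568). That call was lost without wild-type array 1 (0.22, median -0.1) or wild-type array 2 (0.12), and with the mean of probe sets (0.17). Cell cycle genes fell with a median of -0.18 and 17 of 22 lower (camera, adjusted p = 0.028; adjusted p = 0.26 with an estimated correlation), led by Ccna2 (-0.32, SE 0.238), Cdk1 (-0.39, SE 0.316) and Aurka (-0.82, SE 0.748), with Ccnd2 at 0.26 (SE 0.263). It was lost without wild-type array 1, 2 or 3 (0.26, 0.069 and 0.069) and without mutant array 1 or 3 (0.60 and 0.22). In these 3 lists limma called 0 members over all genes and 0 adjusted over the list alone, with 0 at an unadjusted p under 0.05.

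Markers of supporting and basal cells shifted the other way. Genes of sustentacular cells and Bowman glands rose as a set, with 14 of 16 higher and a median of 0.19 (camera, adjusted p = 0.013; adjusted p = 0.53 with an estimated correlation), led by Sec14l3 (0.59, SE 0.367), Ermn (0.60, SE 0.593), the mucin Muc5b (0.29, SE 0.323) and Fmo2 (0.40, SE 0.457). Within the pairs of arrays with the same number the medians were -0.12, 0.18 and 0.61, and 0 of the 16 genes were higher in each pair. The call was lost without wild-type array 2 (0.072), wild-type array 3 (0.90, median -0.06) or mutant array 2 (0.13), and without both arrays numbered 3 (0.73). Genes of horizontal basal cells, the reserve stem cells of the epithelium, rose with 8 of 9 higher and a median of 0.18 (camera, adjusted p = 0.021; adjusted p = 0.54 with an estimated correlation), led by Trp63 (0.50, SE 0.311), Krt15 (0.97, SE 0.712), Krt17 (0.74, SE 0.881) and Krt5 (0.37, SE 0.55). Within the pairs of arrays with the same number their medians were 1.06, -1.18 and 1.15, beside 1.03, -5.05 and 0.80 for squamous epithelium. Their median log2 levels on arrays 1, 2 and 3 were 8.26, 9.44 and 7.86 in wild type and 9.85, 8.27 and 8.78 in mutant, beside 5.25, 9.23 and 5.44, and 7.66, 4.62 and 7.47, for squamous epithelium, so both lists were highest on wild-type array 2 and mutant arrays 1 and 3. The call was lost without wild-type array 1 or 3 (0.22 and 0.37) and without mutant array 1 or 3 (0.64, median -0.03, and 0.10). In both lists limma called 0 members over all genes and 0 adjusted over the list alone, with 0 at an unadjusted p under 0.05.

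Of the 29 lists, 10 were called by camera with the preset correlation, 8 lower and 2 higher. The count became 5 (4 lower) without mutant array 1 and 17 (9 lower) with array weights. With an estimated correlation 0 were called, and with fry 0. With the replicate number as a block, the 10 were called with the preset correlation and 0 with an estimated one. Their camera adjusted p then lay between 0.45 and 0.78 (0.45 for mature neurons). Camera with an estimated correlation rests on the residual degrees of freedom, of which the block leaves fewer.

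**Figure D3:**
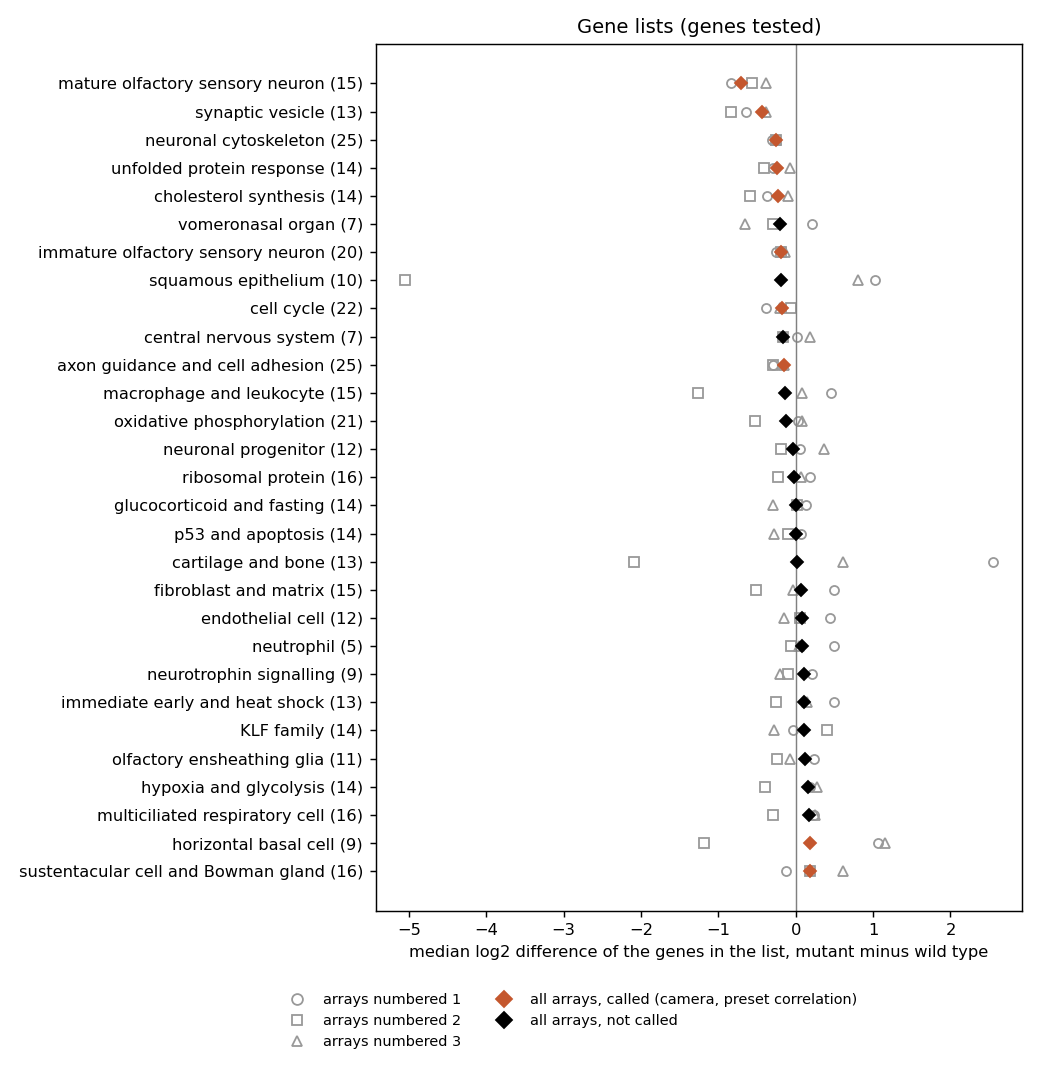
Median log2 difference, mutant minus wild type, of the tested genes in each of 29 lists; filled diamonds use all arrays and open symbols compare the arrays with 1 replicate number each. Mature olfactory neuron, synaptic vesicle and neuronal cytoskeleton medians lie below 0 for each number, while those of squamous epithelium run from -5.05 to 1.03.

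The other 19 lists were not called by camera. Immediate early and heat shock genes had a median of 0.10 (adjusted p = 0.08), oxidative phosphorylation -0.12 (0.082), endothelial cells 0.08 (0.12) and multiciliated respiratory cells 0.17 (0.12). Neutrophil genes had a median of 0.08 (0.21), hypoxia and glycolysis 0.16 (0.30), fibroblast and matrix 0.07 (0.57) and olfactory ensheathing glia 0.12 (0.58). Macrophage and leukocyte genes had a median of -0.14 (0.75) and the KLF family 0.11 (0.75), with Klf4 at 0.59 (SE 0.435) and Klf16 at -0.42 (SE 0.371). Squamous epithelium had a median of -0.19 (0.19) and cartilage and bone 0.01 (0.69). In 7 lists the signs of median, mean and test differed or the median was 0.00. Median and mean were -0.16 and 0.13 for the central nervous system (0.57), 0.00 and -0.02 for glucocorticoid and fasting (0.75), 0.00 and -0.08 for p53 and apoptosis (0.75), and -0.21 and 0.03 for the vomeronasal organ (0.75). They were -0.04 and -0.06 for neuronal progenitors, whose test pointed up (0.82), -0.02 and 0.01 for ribosomal proteins (0.83), and 0.10 and -0.06 for neurotrophin signalling (0.95). In the last list Bdnf differed by -1.22 (SE 0.772). Some of these lists were called by camera when 1 array was left out. Without wild-type array 3 these were higher for glucocorticoid and fasting (0.00038), the KLF family (0.00073), immediate early and heat shock (0.0078), neutrophils (0.0078) and fibroblast and matrix (0.041), and lower for oxidative phosphorylation (0.01). Without mutant array 2 they were higher for neutrophils (0.0042), immediate early and heat shock (0.021) and hypoxia and glycolysis (0.043). Without mutant array 3, oxidative phosphorylation (0.017) and squamous epithelium (0.017) were lower. Cartilage and bone, and fibroblast and matrix, were higher without wild-type array 2 (5e-05 and 0.011) and lower without wild-type array 1 (0.0095 and 0.0024), where squamous epithelium was also lower (0.0038).

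Olfactory receptor genes, of which each neuron expresses very few, were tested without the dim filter. Of 39 measured, 23 were lower, with a median of -0.17 (camera, p = 0.11; p = 0.2 with an estimated correlation), and 7 lay above the dim threshold. Olfr672 differed by -1.18 (SE 0.653) and Olfr159 by 0.94 (SE 0.415). By limma 0 receptor genes passed, with 0 at an unadjusted p under 0.05. The camera p became 0.022 without normalization between arrays, 0.014 without wild-type array 2 and 0.019 without mutant array 2.

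Genes within 10 Mb of Klf7 were examined because flanking sequence of the strain in which a mutation was made can travel with it. The 80 genes tested there had a median of -0.01 (camera, p = 0.65; p = 0.83 with an estimated correlation). By limma 0 of them passed, and 1, Map2, had an unadjusted p under 0.05, against 74 of 12622 elsewhere (Fisher's exact test, p = 0.38). Without mutant array 3 the camera p was 0.026. The direction by camera turned from up to down without wild-type array 3 (camera p of 0.56) or mutant array 2 (0.053), and within 5 Mb (0.92) or 20 Mb (0.51).

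Lists with under 5 genes tested are given as values. Of CDK inhibitors 4 of 7 were tested, Cdkn1a and Cdkn1b as above, with Cdkn1c at -0.09 (SE 0.561) and Cdkn2d at -0.60 (SE 0.747). Of erythroid genes 4 of 16 were tested; Hbb-b2 had means of 10.12 ± 0.62 and 10.52 ± 0.36 in wild type and mutant. Of skeletal muscle genes 4 of 16 were tested, of which Ckm had means of 6.79 ± 0.29 and 7.10 ± 0.56, and Tnnt1 6.93 ± 0.50 and 6.44 ± 0.74. Most of those left out as dim were lower in the mutant, such as Mylpf (-1.47, SE 1.138) and Acta1 (-1.04, SE 0.546). Both were highest on wild-type array 3. Among the dim muscle genes only Des (0.68, SE 0.212) and Myh3 (0.16, SE 1.074) were higher. Of sex-linked genes 2 of 5 were tested. Xist lay at 3.65 on wild-type array 3 and 5.53 on mutant array 2, with the Y-linked Eif2s3y at 10.24 and 7.82. On the other 4 arrays Xist lay between 10.61 and 11.13 and Eif2s3y between 4.04 and 4.95. In these genes 1 array of each group thus differed from the rest, so the arrays numbered 2, and those numbered 3, differed within their pair. The labels do not give the sex of the pups, which was not a covariate.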

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

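Leaving out both arrays numbered 3 was chosen after seeing the data; all other alternatives were set before. The count of genes passing the limma threshold was 0 under all 20 alternatives, where the count at an unadjusted p under 0.05 ran from 41 to 212. Across alternatives, 450 of 578 list values, 547 of 550 values of named genes and 43 of 56 Klf7 values kept their direction and their side of the threshold. The mature olfactory neuron, neuronal cytoskeleton, synaptic vesicle, immature olfactory neuron and unfolded protein response lists stayed below an adjusted p of 0.05 in each of 12 alternatives that kept camera's preset correlation. Their adjusted p ran from 3.7e-17 to 2.3e-09, 2.1e-14 to 5.8e-07, 3.8e-09 to 2e-05, 0.00014 to 0.027 and 5.7e-05 to 0.031. The first 3 were also called without each single array, with adjusted p of 1.5e-13 to 1.3e-05, 3.7e-09 to 1.3e-05 and 8.1e-07 to 0.00041. Signal over background limits genes near the floor, where differences are understated. Except where stated, the cause of each change was not tested.

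With the replicate number as a block, 157 genes had an unadjusted p under 0.05; the block also brought Cnga2 and Cartpt past the threshold over the mature neuron list alone, and changed no other call with camera's preset correlation of a list, a Klf7 probe set, a named gene, the receptor genes or the genes near Klf7.

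With an estimated correlation 0 lists were called, and adjusted p was 0.085 for mature neurons, 0.08 for neuronal cytoskeleton, 0.08 for synaptic vesicle, 0.14 for immature neurons, 0.26 for unfolded protein response, 0.37 for cholesterol synthesis, 0.53 for sustentacular cells and Bowman glands, 0.54 for horizontal basal cells, 0.26 for cell cycle and 0.28 for axon guidance and adhesion. With fry 0 lists were called, and adjusted p for the same lists in that order was 0.18, 0.18, 0.18, 0.42, 0.8, 1, 1, 1, 0.42 and 0.8; neuronal progenitors turned down (1). The estimated correlations of the 10 lists lay between -0.012 and 0.381. They were above the preset 0.01 for 8 lists and below it for immature neurons (-0.012) and cell cycle (-0.004). For immature neurons and cell cycle a higher correlation therefore cannot account for the lost call. Other reasons for the lost calls were not tested.

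Without the dim filter, 191 genes had an unadjusted p under 0.05, out of more genes tested, and cell cycle (0.051) and horizontal basal cells (0.091) were no longer called, while immediate early genes were (0.037), as also with a floor at the 10th percentile (0.031). With the lowest 60% left out, cell cycle was lost (0.16) and p53 and apoptosis turned up (0.51). Without normalization between arrays, 50 genes had an unadjusted p under 0.05 and the receptor genes (camera, 0.022) and the multiciliated cell list (0.049) passed. With array medians set equal, that count was 41, neuronal progenitors turned down (0.92) and the vomeronasal list up (0.99). Without an intensity trend, horizontal basal cells (0.063) and sustentacular cells (0.054) were lost. With array weights, 131 genes had an unadjusted p under 0.05 and 17 lists were called: cartilage (0.0077), endothelial cells (0.017), fibroblasts (0.00094), hypoxia (0.028), immediate early genes (0.0021), the KLF family (0.043), neutrophils (0.0021) and oxidative phosphorylation (0.013) were gained, sustentacular cells were lost (0.79), and macrophage (0.34), p53 (0.85) and vomeronasal (0.38) lists turned up. With the mean of probe sets, axon guidance (0.25), cholesterol synthesis (0.17) and horizontal basal cells (0.059) were lost, the KLF family turned down (0.96), p53 (0.96) and vomeronasal (0.74) lists turned up, the genes near Klf7 turned down (camera, 0.97), and Map2 differed by 0.1. Genes within 5 Mb and within 20 Mb of Klf7 pointed down (camera p of 0.92 and 0.51).

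Without both arrays numbered 3, 120 genes had an unadjusted p under 0.05 and 10 lists were called. Axon guidance (0.25), cell cycle (0.081), horizontal basal cells (0.36) and sustentacular cells (0.73) were lost, and 4 lists were gained: oxidative phosphorylation (0.00014) and squamous epithelium (0.0027, median -1.13) on the lower side and endothelial cells (0.017) and the KLF family (0.017) on the higher. Neuronal progenitors (0.77) and ribosomal proteins (0.77) turned down, and p53 (0.45) and vomeronasal (0.37) lists turned up. Klf7 differences were -2.81, -2.32, -2.01 and -1.56 for 1419354_at, 1419355_at, 1419356_at and 1449439_at, none past the threshold with 2 arrays in each group.

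Leaving out 1 array at a time, 67 to 212 genes had an unadjusted p under 0.05 and 5 (without mutant array 1) to 12 lists were called. Adjusted p ran from 0.021 to 0.37 for axon guidance, 0.0047 to 0.6 for cell cycle, 9.4e-05 to 0.22 for cholesterol synthesis, 0.00016 to 0.64 for horizontal basal cells, 0.0023 to 0.11 for immature neurons, 0.0018 to 0.9 for sustentacular cells and 0.0014 to 0.1 for unfolded protein response. Among lists not called on all arrays that changed direction at least once, it ran from 5e-05 to 0.85 for cartilage and bone, 0.0024 to 0.83 for fibroblast and matrix, 0.00038 to 0.64 for glucocorticoid and fasting, 0.043 to 0.93 for hypoxia and glycolysis, 0.00073 to 0.94 for the KLF family, 0.064 to 0.99 for macrophages, 0.38 to 0.86 for neuronal progenitors, 0.09 to 0.92 for neurotrophin signalling, 0.069 to 0.95 for ensheathing glia, 0.01 to 0.93 for oxidative phosphorylation, 0.31 to 0.96 for p53, 0.084 to 0.97 for ribosomal proteins, 0.0038 to 0.49 for squamous epithelium and 0.069 to 0.96 for the vomeronasal organ. Lists that kept their direction and were called without some array ran from 0.0042 to 0.93 for neutrophils and 0.0078 to 0.7 for immediate early genes. The camera p of the receptor genes ran from 0.014 to 0.58 and that of the genes near Klf7 from 0.026 to 0.76. Klf7 differences ran from -3.44 to -2.75 for 1419354_at, -2.65 to -1.73 for 1419355_at, -2.86 to -1.63 for 1419356_at and -2.6 to -1.66 for 1449439_at, Cdkn1a from -0.89 to 0.09 and Omp from -0.7 to 0.02.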

Other observations

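The count of splits for the genes passing the threshold and the comparison of immature with mature neuron genes were tests chosen only after the result was seen.

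Markers of tissue next to the olfactory epithelium varied widely from array to array. The squamous epithelium list had median log2 levels of 5.25, 9.23 and 5.44 on wild-type arrays 1, 2 and 3, and 7.66, 4.62 and 7.47 on mutant arrays 1, 2 and 3. Cartilage and bone genes had 5.94, 9.29 and 6.21 on the wild-type arrays and 7.95, 6.63 and 7.79 on the mutant arrays. Sustentacular cell and Bowman gland genes had steadier medians, between 10.39 and 10.88 on all 6 arrays. Compared gene by gene without the dim filter, wild-type array 3 differed from the other wild-type arrays by a median of -0.55 in this list. Of 12703 genes, 2004 (15.8%) moved the same way within each of the pairs of arrays with the same number, 802 higher and 1202 lower in the mutant, where chance gives 25%. The differences within pairs 1 and 2 correlated at -0.32 across genes, those within pairs 1 and 3 at 0.15, and those within pairs 2 and 3 at -0.26. Among 136 gene families formed by symbol stem, a grouping added after the data were seen, camera called 0; the synaptotagmin stem Syt had the smallest p, 0.0043, with an adjusted p of 0.52, a median of -0.27 and 8 of 10 lower.

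Neuronal genes were lower in the mutant arrays. The 53 genes of the mature olfactory neuron, neuronal cytoskeleton and synaptic vesicle lists had a mean log2 difference of -0.462. Of 10 splits into 3 and 3 arrays only the real 1 gave a shift as large (highest other 0.318), where 10 splits cannot give a share under 0.05. These 3 lists had the smallest camera p of all lists on the real split. Their choice favours that split, so its rank says nothing about chance. A smaller share of olfactory neurons of every stage in the mutant dissections may account for the shift. It would lower immature and mature markers alike if both were equally particular to neurons. The immature median lay 0.52 above the mature median (95% bootstrap interval over list members 0.01 to 0.85), but the means differed by 0.30 with an interval of -0.05 to 0.64. Over arrays, the gap between the lists' means was 0.30 larger in the mutant (SD 0.12 in each group, exact permutation p = 0.1, the smallest possible). This goes against an equal fall of both lists but, with the interval of the means including 0, does not settle it. Whether the members of both lists are equally particular to neurons was not tested. Within the immature list differences ran from -1.28 for Crmp1 to 0.64 for Stmn4, so the gap need not bear on the share of neurons. The largest falls of that list lay among the 10 genes that are also in the cytoskeleton list. The genotype, which the comparison contrasts, stays open as a source of the shift and is not a rival to a smaller share of neurons. RNA of whole tissue cannot tell such a share from lower levels within each neuron.

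The arrays numbered 3 stand apart from the other 4. Weaker signal on them was predicted to leave little shared deviation among bright genes. Their deviations correlated at 0.45 among the brightest 3176 genes and at 0.66 among the dimmest 3176. After quantile normalization weaker signal can still leave shared deviations in bright genes, so this does not exclude it. Deposited totals were lowest on wild-type array 3 (10064207) and mutant array 3 (11056397), against 13081397 or more on the others. These arrays also had the most values at 0 (6.35% and 5.97%). Other tissue in the dissections numbered 3 stays open: the highest shared excess among 6 lists of non-olfactory tissue was 0.57 on the log2 scale, for erythroid genes, 1.33 above the other wild-type and 0.57 above the other mutant arrays, with Hbb-b2, the brightest, at 10.71 on wild-type array 3 against 9.47 and 10.18, and at 10.83 on mutant array 3 against 10.13 and 10.60. Lists outside those 6 had larger shared excesses, neutrophil genes at 0.98 and 0.85 and glucocorticoid and fasting genes at 0.75 and 0.68. Skeletal muscle genes lay 1.27 and 0.15 above, and squamous epithelium -1.64 and 1.04. Both genotypes have an array numbered 3, but Xist lay at 3.65 on wild-type array 3 and at 10.96 on mutant array 3. Beyond tissue content no biological explanation, sex included, was tested.

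The real split gave 10 called lists of 29, the highest other split gave 9, and 1 of the 10 splits gave as many. With 10 splits no share under 0.05 can be reached. The mature neuron list had a camera adjusted p of 7.6e-13 on the real split. Camera also called that list on splits that mix the genotypes, with adjusted p of 0.0086, 0.029 and 0.033. For genes passing the limma threshold the real split gave 0, with 76 at an unadjusted p under 0.05, and the highest other split gave 3; since no split can give fewer than 0, all 10 count as giving as many, and this says nothing about chance. Among the 4 splits that part all pairs of same-numbered arrays, the highest values other than the real ones were 9 lists and 811 genes at an unadjusted p under 0.05 in 1 split, whose neuronal shift was 0.078, and a neuronal shift of 0.30 in another, with 4 lists and 143 genes. The split that sets wild-type arrays 1 and 2 with mutant array 1 against the rest gave 1844 genes at an unadjusted p under 0.05, many times the real 76, and has both arrays numbered 3, with mutant array 2, on 1 side. The split with 811 genes, which also gave the 3 genes called, parts the arrays numbered 3 and sets wild-type arrays 1 and 3 and mutant array 2, the lowest in squamous epithelium and cartilage genes, against the rest, so the arrays differ along more than 1 line.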
